A study of Mus musculus with 8 samples.

How the data were processed

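Gene expression was measured by RNA sequencing in 8 libraries of ischemic tibialis anterior muscle, 4 from mice on placebo chow and 4 from mice on praliciguat chow. Per the labels' protocols, RNA was extracted with Tri Reagent from snap-frozen homogenised muscle and made into libraries with a stranded mRNA kit (KAPA). The submitters' processing notes name FastQC, Trimmomatic, STAR 2.5.3a, RSEM 1.2.28 and the build mm10. The strand setting used in counting is not given in the sources used here, so genes with an antisense partner are uncertain.

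The authors deposited 1 table per library with 24848 gene symbols. Its expected count column, per the file headers, holds RSEM's estimated read counts per gene, in which reads shared by related genes are divided by the model. Between 0.765% and 0.930% of genes per library had an expected count that was not whole (tolerance 0.001). The deposited TPM column holds RSEM's length-scaled values, per the file headers, and was used for alternatives only. The deposited effective length, per the file headers, is the gene length over which reads can start and served as an offset in 1 alternative. Deposited FPKM values were not used here. Reads of near-identical genes (myosin heavy chains, Hspa1a and Hspa1b, globins, H2-Q genes) depend on this division and are uncertain.

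Groups came from the labels. Replicates were numbered in accession order, which pairs nothing across groups. The numbers in the sample titles form a lower run and an upper run with 2 libraries of each group in each; the labels do not say what they mean. Total expected counts were 21099764, 29635817, 27791709 and 28167928 for placebo replicates 1 to 4 and 27271020, 27820499, 31896205 and 28270125 for praliciguat replicates 1 to 4. A gene with 0 counts can lie up to 0.0875 to 0.134 CPM, from 3 counts in the deepest and the shallowest library, for counting error only. Over 13351 genes with at least 100 counts in all, the chi-square of paired libraries per degree of freedom was 21.9 to 136 within groups, so no 2 libraries agreed within sampling noise.

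Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling, and the quasi-likelihood F test with robust dispersion, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit held the group and no covariate. CPM values are counts relative to the TMM-scaled library size; a fold change is praliciguat against placebo. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, two-sided, with adjustment over 29 lists. The test with an estimated correlation and fry were alternatives. A list score is the mean log2 CPM (prior count 2) of its members, compared by an exact two-sided permutation test over all 70 groupings.

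Of 31 lists fixed before the data were examined, 29 were tested. They covered nitric oxide and cGMP signalling, angiogenic factors, fibre types, regeneration, denervation, metabolism, hypoxia, stress, and markers of endothelial, smooth muscle, immune, fat, Schwann, red blood and skin cells. Of the keratinocyte list 4 members were tested, and of the mitochondrial transcript list 0 members had a row in the tables. The rule for naming genes was fixed at the same time. It took the 10 genes of lowest p in each direction, passing over symbols that are Gm or LOC plus digits or end in Rik, microRNAs and small RNAs. It added the members of each list that passed over all genes, at most 4 of lowest p, or else the 2 members of lowest p. It always named Gucy1a1, Gucy1b1, Prkg1, Pde5a, Nos3, Vegfa, Kdr, Pecam1, Cdh5, Pax7, Myh3 and Lepr. Coordinates are those of RefSeq on GRCm38, the assembly of mm10; 13308 of the 13569 tested symbols matched.

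The test was checked on simulated counts with the libraries' means, sizes and dispersions. Of 97 genes changed by 1 on the log2 scale 57 were recovered (58.8%), and of 97 changed by 2, 92 were recovered (94.8%), among 13443 genes, with 8 unchanged genes called. In a simulation that lowered the slow fibre list by 1, camera called that 1 list of 29. Each gene was drawn independently, without further structure among the libraries. These simulations therefore cannot tell how often camera calls lists whose members vary together. Nor do they give the recovery in the real libraries, where edgeR called 0 genes. Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, no count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, the fit without robust dispersion, effective lengths as an offset, limma on log2(TPM + 1) and log2(TPM + 0.1), the run as a block, each library left out, and an adjusted p under 0.1. Leaving out praliciguat replicates 3 and 4 together, the estimated correlation with libraries left out, and the naming of Myh7, Tnnc1, Tpm3, Casq2 and Myh4 were chosen after seeing the data.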

Results

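RNA sequencing of ischemic tibialis anterior muscle, a leg muscle of the mouse, was compared between 4 libraries from mice on control chow (placebo) and 4 libraries from mice on chow with praliciguat. Praliciguat stimulates soluble guanylate cyclase, the nitric oxide receptor that makes cGMP. All animals were labelled as male Leprdb/db mice, which lack a working leptin receptor and are obese and diabetic. Blood flow to one hind limb had been interrupted by surgery, and muscle was taken 28 days later. The drug diet held 75 ppm praliciguat, aimed at the plasma level of a 10 mg/kg/day oral dose, and was given for 31 days from day -3. Total expected counts ranged from 21099764 in placebo replicate 1 to 31896205 in praliciguat replicate 3, over 24848 genes, of which 13569 were tested. The labels do not say outright that each library is a separate mouse, so p-values measure the spread between these libraries.

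The question of the comparison was which transcripts differ in ischemic muscle when praliciguat is given. Genes of slow muscle fibres were lower with praliciguat. As a list, the 16 slow fibre genes fell by a mean of 1.66 on the log2 scale (median -1.50), and 15 of the 16 had a fold change below 0. Myl2, the slow myosin regulatory light chain, had 175 ± 93.7 CPM in placebo and 13.1 ± 5.29 CPM with praliciguat (SD, n = 4 each), a 13.4-fold lower level (log2 fold change -3.75 ± 0.53 SE). Tnnt1 and Tnni1, the slow isoforms of troponin T and troponin I, were at 183 ± 77.2 against 23.1 ± 5.80 CPM and at 51.2 ± 18.9 against 7.16 ± 2.70 CPM (SD, n = 4). Atp2a2, the calcium pump of slow fibres, was at 296 ± 103 against 73.4 ± 17.5 CPM (log2 fold change -2.01 ± 0.28 SE). In 8 of the 16 genes, these 4 among them, all 4 praliciguat libraries lay below all 4 placebo libraries.

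The slow fibre list was called lower by camera with a preset correlation (adjusted p = 1.03e-49 over 29 lists). It was the 1 list of the 29 still called with an estimated correlation (adjusted p = 0.009 with an estimated correlation). The rotation test fry gave an adjusted p of 0.0206 for the same list. Of its 16 members, 9 were lower when adjusted over the list alone and 0 when adjusted over all genes tested, where edgeR gave Tnnt1 and Tnni1 an adjusted p of 0.0777 each. DESeq2 called 9 of the members lower over all genes. Myh7 (-3.39 ± 0.56), the slow myosin heavy chain, Tnnc1 (-3.17 ± 0.45), slow troponin C, and Tpm3 (-2.29 ± 0.42), slow tropomyosin, were picked out here after their values were seen. Casq2, a calsequestrin of slow and cardiac muscle, was the member with a fold change above 0 (0.30 ± 0.23 SE).

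The mean log2 CPM of the list was 6.47 ± 0.335 in placebo and 4.78 ± 0.342 with praliciguat (SD, n = 4), without overlap (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give; 0.276 after adjustment over 29 lists). The sample titles carry numbers that fall into a lower and an upper run, each with 2 libraries per group. Within the lower run the score differed by -1.66 and within the upper run by -1.72. With the estimated correlation the call ended when praliciguat replicate 3 was left out (adjusted p = 0.0881) and when praliciguat replicates 3 and 4 were both left out (adjusted p = 0.305), an alternative chosen after seeing the data. Each of the other 7 libraries could be left out with this adjusted p between 0.0103 and 0.0391. The mean log2 fold change of the list was -1.71 without praliciguat replicate 3, against -1.66 with all 8 libraries. It was -1.57 without praliciguat replicates 3 and 4. Camera with the preset correlation called the list lower in both cases (adjusted p = 1.60e-29 and 1.73e-15).

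**Figure D1:**
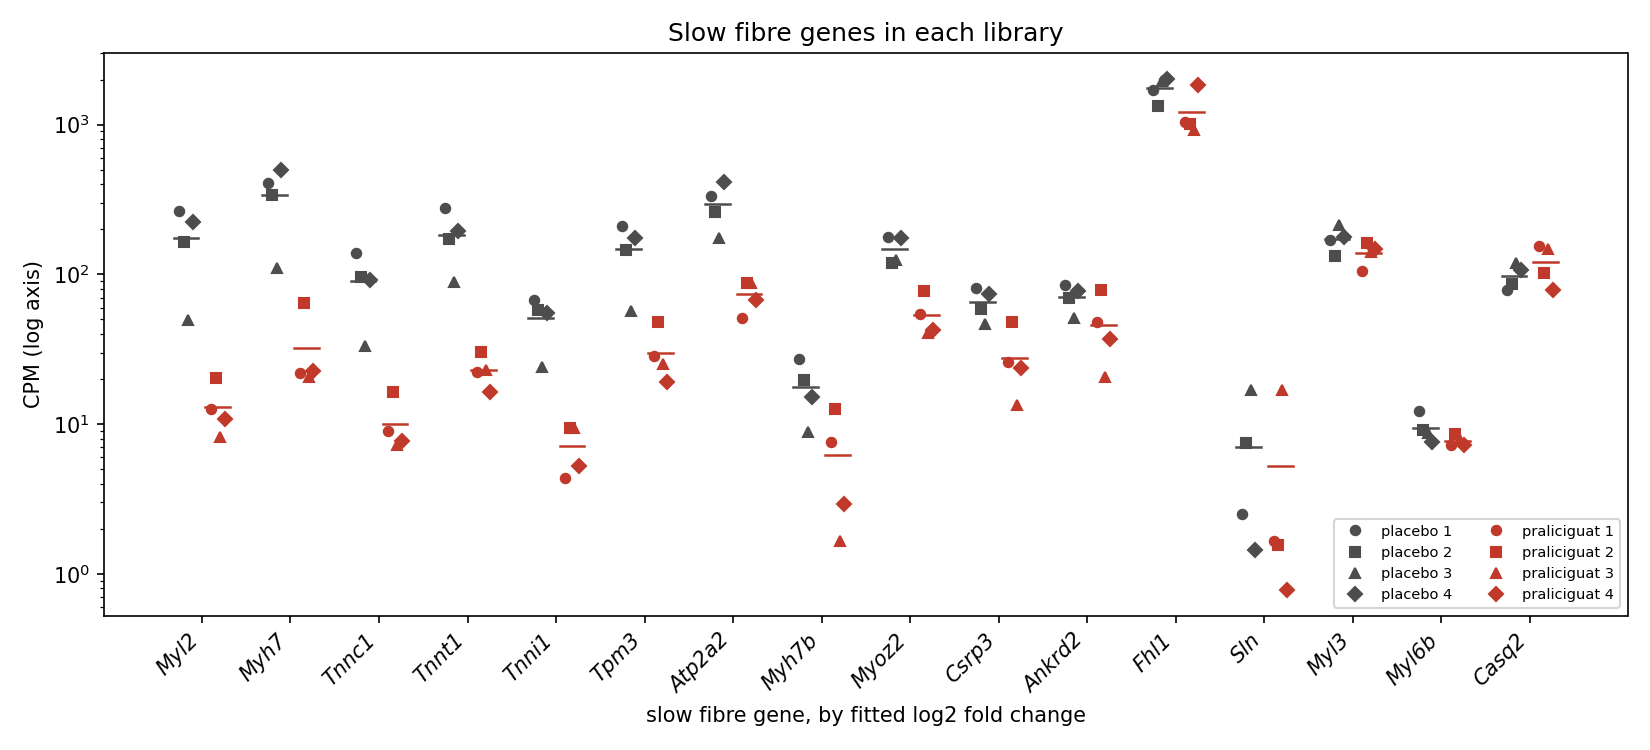
CPM (log axis) of the 16 slow fibre genes in each of the 8 libraries, with placebo in grey and praliciguat in red. Bars are group means of 4 libraries, markers are replicates, and genes are ordered by fitted log2 fold change from Myl2 (-3.75) to Casq2 (0.30).

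Among the 4 adult myosin heavy chains, which mark fibre types from slow to fastest, the share of Myh7 was 0.561 ± 0.250% in placebo and 0.0483 ± 0.0234% with praliciguat (SD, n = 4). Myh2, the chain of fast oxidative fibres, took 5.0 ± 1.41% against 1.54 ± 0.317% (SD, n = 4). Both shares separated the groups (exact two-sided permutation p = 0.0286 each; 0.0571 after adjustment over 4 shares). Myh1 took 20.7 ± 5.53% against 13.6 ± 2.71%, and Myh4, the chain of the fastest fibres, 73.7 ± 6.77% against 84.8 ± 3.01% (exact two-sided permutation p = 0.0571 each, SD, n = 4). These genes lie close in sequence, so shares rest on how reads common to them were divided. The list of 18 fast fibre genes was not called (mean log2 fold change 0.01, camera adjusted p = 0.584), with 1 member lower when adjusted over the list alone and 0 over all genes tested. Without praliciguat replicate 3 its camera adjusted p was 0.0499 (mean 0.09). Without praliciguat replicates 3 and 4 it was 0.0235 (mean 0.11), and 0.759 with an estimated correlation. The 1 lower member was Myh2 (log2 fold change -1.56 ± 0.22 SE, edgeR adjusted p = 0.0777), and Myh1 followed with -0.46 ± 0.20 (edgeR adjusted p = 0.859). Myh1 differed by -0.087 within the lower run of title numbers and by -0.84 within the upper run. For Myh2 these differences were -1.14 and -1.95. The fry test for change in either direction called 4 lists: fast and slow fibre genes (adjusted p = 0.00738 each) and angiogenic factors and heat shock proteins (0.00138 each).

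For single genes, edgeR called 0 higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.0777. At an unadjusted p under 0.05 there were 778 genes, 265 higher and 513 lower, where chance gives 678. DESeq2 called 13 genes higher and 113 lower, and had 944 at an unadjusted p under 0.05. The limma-voom test called 0 higher and 2 lower (Gdf11 and Tnnt1) with 821 at an unadjusted p under 0.05, and 0 and 2 with quality weights. In 524 genes (3.86%) the groups did not overlap, where chance gives 2.86% over both directions together. Of these, 345 were lower and 179 higher with praliciguat. With the run of the title numbers as a block, edgeR called 0 higher and 3 lower (Tnnt1, Pdlim1 and Dusp18). Without placebo replicate 3 it called 5 lower, and without praliciguat replicates 3 and 4 it called 6 higher and 79 lower. Praliciguat replicates 3 and 4 both belong to the upper run. The fit without them set praliciguat of the lower run against placebo of both runs, so group and run were partly confounded in it.

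The 10 genes of lowest p among those lower missed the threshold in edgeR, with adjusted p from 0.0777 to 0.0945. Gdf11, a growth factor of the TGF-beta family, was at 13.7 ± 0.941 CPM in placebo and 4.84 ± 1.12 CPM with praliciguat (SD, n = 4; log2 fold change -1.50 ± 0.17 SE). Nmrk2, a muscle nicotinamide riboside kinase, was at 314 ± 23.8 against 180 ± 20.3 CPM, and Pdlim1, a PDZ and LIM domain protein of the actin cytoskeleton, at 59.4 ± 8.14 against 31.2 ± 2.64 CPM. Dusp18, a dual-specificity phosphatase, and Npnt, a matrix protein, had log2 fold changes of -1.31 ± 0.17 and -1.05 ± 0.14 (SE). Myh2, Tnnt1, Tnni1, Atp2a2 and Myl2 made up the rest of the 10. DESeq2 called all 10 lower, on the same counts from which they were picked. In RefSeq coordinates of mm10, Gdf11 lies on chromosome 10 from 128880524 to 128891718, Tnnt1 on chromosome 7 from 4504569 to 4515975, Tnni1 on chromosome 1 from 135783033 to 135810989 and Myl2 on chromosome 5 from 122092724 to 122113473. Counts are per gene over its transcripts.

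Among genes higher, the 10 of lowest p under the naming rule, which passes over 2 symbols ending in Rik here, missed the threshold in edgeR too, with adjusted p from 0.115 to 0.352. Lrg1, a secreted leucine-rich glycoprotein on chromosome 17 from 56119678 to 56121946, was at 30.5 ± 2.17 CPM in placebo and 48.4 ± 5.96 CPM with praliciguat (SD, n = 4; log2 fold change 0.67 ± 0.11 SE). Met, the receptor of hepatocyte growth factor, was at 17.1 ± 0.423 against 22.3 ± 0.839 CPM. Kcnc4, a voltage-gated potassium channel, was at 136 ± 28.2 against 203 ± 11.9 CPM, and Bace1, the beta-secretase, at 25.7 ± 3.84 against 38.4 ± 5.10 CPM. Plekhh3, Trim13, Mtap and Nek6 had log2 fold changes of 0.39, 0.46, 0.48 and 0.52. Spns3 (1.28) and H2-Q7 (1.07) were low, at 1.18 and 1.30 CPM in placebo. H2-Q7 has near-identical relatives and its count is uncertain. In all 10 genes every praliciguat library lay above every placebo library, and DESeq2 called all 10 higher. The 10 were picked by p from these same libraries, so neither result is independent support.

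The list of transcripts of the pathway that the drug acts on was not called. RNA levels do not measure cGMP or the activity of the enzymes. Of 27 genes of nitric oxide and cGMP signalling, 16 had a fold change below 0 (mean log2 fold change -0.03, camera adjusted p = 0.173). When adjusted over the list alone 1 was lower, and 0 passed over all genes tested. The subunits of soluble guanylate cyclase, Gucy1a1 and Gucy1b1, were at 16.6 ± 4.20 against 15.6 ± 2.53 CPM and at 11.04 ± 2.02 against 10.3 ± 0.954 CPM (SD, n = 4). Prkg1, the cGMP-dependent kinase, had a log2 fold change of -0.27 ± 0.27 and Pde5a, a phosphodiesterase that degrades cGMP, of -0.25 ± 0.22 (SE). With 1 library left out they ranged from -0.45 to -0.10 and from -0.38 to -0.010. Prkg1 differed by 0.36 within the lower run of title numbers and by -1.01 within the upper run. Nos3, the endothelial nitric oxide synthase, was at 24.0 ± 2.67 CPM in placebo and 15.7 ± 1.92 CPM with praliciguat (log2 fold change -0.61 ± 0.12 SE, edgeR adjusted p = 0.212), and Pde10a had -0.71 ± 0.19. DESeq2 called Nos3 lower.

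Vessel genes lay lower with praliciguat, at small fold changes. Of 24 endothelial genes 23 had a fold change below 0, with a mean of -0.31, and 3 were lower when adjusted over the list alone and 0 over all genes tested. Camera with a preset correlation called the list lower (adjusted p = 1.61e-11), and the call was lost with an estimated correlation (adjusted p = 0.447 with an estimated correlation) and with fry (0.329). Cdh5 and Pecam1, junction proteins of endothelium, had log2 fold changes of -0.38 ± 0.14 and -0.32 ± 0.14 (SE), Ptprb and Tie1 of -0.46 and -0.45. The endothelial score was 5.11 ± 0.178 against 4.79 ± 0.169 (SD, n = 4; exact two-sided permutation p = 0.0286, 0.276 after adjustment over 29 lists), and -0.35 and -0.29 within the lower and the upper run.

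Of 37 angiogenic factors and receptors 30 had a fold change below 0 (mean -0.26), and 7 were lower and 1 higher when adjusted over the list alone, with 0 over all genes tested. The list was called lower by camera (adjusted p = 2.52e-09; adjusted p = 0.107 with an estimated correlation). Notch4, a Notch receptor of endothelium, was at 65.9 ± 9.34 CPM in placebo and 37.8 ± 5.05 CPM with praliciguat (log2 fold change -0.80 ± 0.13 SE, edgeR adjusted p = 0.118). Vegfa, the main growth factor of endothelium, was at 427 ± 32.7 against 325 ± 32.8 CPM (SD, n = 4; log2 fold change -0.39 ± 0.11 SE, edgeR adjusted p = 0.399), and its receptor Kdr had -0.35 ± 0.22. Met was the member higher over the list alone. Of 17 smooth muscle and pericyte genes 14 were below 0 (mean -0.21), and 0 passed over the list alone or over all genes tested. Camera called that list lower (adjusted p = 0.0151; adjusted p = 0.582 with an estimated correlation), with Smtn at -0.26 and Kcnj8 at -0.32. The call ended without placebo replicate 1 (camera adjusted p = 0.297), praliciguat replicate 3 (0.207) or praliciguat replicate 4 (0.0687), and the mean ranged from -0.28 to -0.064 with 1 library left out. Of 20 hypoxia response genes, 12 were below 0 (mean -0.12) and 0 passed either adjustment. This list was called lower too (adjusted p = 0.0327; adjusted p = 0.582 with an estimated correlation). It was not called without placebo replicates 3 or 4 (camera adjusted p = 0.0669 and 0.0606) or praliciguat replicates 3 or 4 (0.196 and 0.285; mean -0.20 to -0.054 with 1 library left out). Vegfa and P4ha1, a collagen prolyl hydroxylase (-0.40 ± 0.16 SE), had its lowest p.

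Heat shock proteins lay lower: 15 of 17 had a fold change below 0 (mean -0.33), 5 were lower when adjusted over the list alone and 0 over all genes tested. Camera called the list lower (adjusted p = 8.90e-09; adjusted p = 0.107 with an estimated correlation). Cryab, the small heat shock protein alpha-B crystallin, was at 799 ± 117 against 447 ± 56.1 CPM (SD, n = 4; log2 fold change -0.84 ± 0.14 SE, edgeR adjusted p = 0.118). Hspa1b had -1.06 ± 0.25 and shares nearly all its sequence with Hspa1a. Of 35 genes of fatty acid oxidation 21 were below 0 (mean -0.10), 1 was lower over the list alone and 0 over all genes tested. Camera called the list lower (adjusted p = 0.0327; adjusted p = 0.796 with an estimated correlation). The call ended without any one of placebo replicates 2, 3 and 4 and praliciguat replicates 3 and 4 (camera adjusted p from 0.0606 to 0.688; mean -0.0044 without praliciguat replicate 4 and -0.195 without praliciguat replicate 1). Without praliciguat replicates 3 and 4 it was called with a mean of 0.067 (camera adjusted p = 0.0446, and 0.759 with an estimated correlation). Its score differed between the groups by 0.076 within the lower run and by -0.36 within the upper run. Eci1, an enoyl-CoA isomerase of mitochondria, had -0.62 ± 0.13 and Acaa2, a thiolase, -0.32 ± 0.14. Of 24 genes of glycolysis and glycogen 17 were above 0 (mean 0.08), with 0 past either adjustment. Camera called it higher (adjusted p = 0.0446; adjusted p = 0.774 with an estimated correlation), with Pygm at 0.27. This call ended without any one of placebo replicates 1, 3 and 4 and praliciguat replicates 1, 2 and 4 (camera adjusted p from 0.053 to 0.297), with the run as a block (0.0652) and with the filter of 1 CPM in 4 libraries (0.0533). The mean ranged from 0.046 to 0.13 with 1 library left out. Of 46 genes of oxidative phosphorylation 37 were below 0, and the mean over all 46 was -0.05 (camera adjusted p = 0.0963). The camera adjusted p was 0.00167 without praliciguat replicate 2, 0.770 with a mean of -0.0034 without praliciguat replicate 3, and 0.00449 on ranks. Ndufb7 was at -0.21 and Sdhc at -0.14.

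In the list of satellite cells and muscle regeneration, 16 of 23 genes had a fold change below 0 (mean -0.32), and 1 was lower and 1 higher when adjusted over the list alone, with 0 over all genes tested. Myh3, the embryonic myosin heavy chain that marks newly formed fibres, was at 36.3 ± 13.99 CPM in placebo and 5.46 ± 4.19 CPM with praliciguat (SD, n = 4; log2 fold change -2.72 ± 0.54 SE, edgeR adjusted p = 0.251). Myod1, a transcription factor of muscle precursors, was at 19.9 ± 4.46 against 32.1 ± 5.47 CPM (0.69 ± 0.18 SE), and Pax7, the satellite cell factor, at 1.94 ± 0.367 against 1.74 ± 0.654 CPM. Camera called the list lower (adjusted p = 0.0374; adjusted p = 0.795 with an estimated correlation). The call ended without any one of placebo replicates 2 and 3 and praliciguat replicates 1, 2 and 4 (camera adjusted p from 0.0706 to 0.854), with the run as a block (0.0723) and with the filter of 1 CPM in 4 libraries (0.0533). The mean was -0.77 without praliciguat replicate 3 and -0.0013 without placebo replicate 3. The list of 21 denervation and atrophy genes was not called (mean -0.09, camera adjusted p = 0.172; 0.00385 without placebo replicate 1), with Ncam1 at -0.75 and Musk at -0.47.

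Markers of immune cells, matrix and fat differed between libraries of a group. The macrophage score was 4.86 in praliciguat replicate 3, 1.87 to 2.76 in the other praliciguat libraries and 2.14 to 3.40 in placebo. Of 23 macrophage genes 22 had a fold change above 0 (mean 0.82), with 0 past either adjustment. Camera called the list higher (adjusted p = 0.0106; adjusted p = 0.796 with an estimated correlation). Without praliciguat replicate 3 the mean was -0.38 (adjusted p = 0.0619), and without placebo replicate 2 the call ended (adjusted p = 0.0524). Aif1 of this list had 1.37 ± 0.91 (SE). The score of 32 fibroblast and matrix genes was 7.01 in praliciguat replicate 3 and 4.63 to 6.04 in the other praliciguat libraries. That list was not called (mean 0.09 and median 0.17, while the camera direction was down, adjusted p = 0.472), and without praliciguat replicate 3 it was lower (mean -0.51, camera adjusted p = 1.96e-09). With an estimated correlation 0 lists were called without that library. Without praliciguat replicate 2 the matrix list was called too with the preset correlation (mean 0.35, camera adjusted p = 0.0203). Ctgf, a matricellular protein, was at 67.9 ± 16.1 against 29.2 ± 16.6 CPM and Tnc, tenascin C, at 14.9 ± 4.38 against 6.29 ± 6.10 CPM (SD, n = 4). Tnc was at 1.53, 1.36, 14.1 and 8.16 CPM in praliciguat replicates 1 to 4. Its log2 fold change ranged from -2.00 to -0.90 with 1 library left out. Of 27 interferon response genes 21 were above 0 (mean 0.21), with Irgm1 at 0.23 and Iigp1 at 0.96. Iigp1 was at 39.2 CPM in praliciguat replicate 1, and its log2 fold change ranged from 0.44 to 1.19 with 1 library left out. Camera called this list higher (adjusted p = 0.0327; adjusted p = 0.796 with an estimated correlation), and its mean was -0.02 without praliciguat replicate 3. The call ended without placebo replicate 4 (adjusted p = 0.853) or praliciguat replicate 1 (adjusted p = 0.103), and with the filter of 1 CPM in 4 libraries (adjusted p = 0.0533). Group differences of the macrophage, matrix and interferon scores turned between the runs of title numbers. They were -0.33, -0.94 and -0.16 within the lower run and 0.98, 0.53 and 0.50 within the upper run.

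Of 20 adipocyte genes 19 had a fold change above 0 (mean 0.71), and 0 passed over the list alone or over all genes tested. The adipocyte list was called higher by camera (adjusted p = 1.27e-08; adjusted p = 0.582 with an estimated correlation). Its score was 7.31 and 7.12 in praliciguat replicates 3 and 4, 6.92 in placebo replicate 3, and 5.41 to 6.15 in the other 5 libraries. Slc7a10, an amino acid carrier of fat cells, and Cfd, the adipokine adipsin, had log2 fold changes of 1.25 ± 0.56 and 1.37 ± 0.62 (SE). The mean was 1.26 without placebo replicate 3 and 0.48 without praliciguat replicate 3, and the list stayed called with any 1 library left out. Without praliciguat replicates 3 and 4 the mean was 0.02 (camera adjusted p = 0.302). Of 14 Schwann cell genes 12 were below 0 (mean -0.38), with Ngfr at 0.79. Camera called this list lower (adjusted p = 0.0118; adjusted p = 0.771 with an estimated correlation). The call ended without placebo replicate 1 (camera adjusted p = 0.281), praliciguat replicate 3 (0.111) or praliciguat replicate 4 (0.154), and the mean ranged from -0.59 to -0.12 with 1 library left out.

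The lists not called by camera with the preset correlation were neutrophils (5 genes, mean 0.32, Mmp9 0.87 and Csf3r 0.89), lymphocytes (5 genes, mean 0.60), MHC class II presentation (8 genes, mean 0.50, Ctss 1.10 and H2-DMb1 0.54) and inflammatory cytokines (18 genes, mean 0.32, Ccl8 2.05 and Icam1 -0.59). Jchain, the joining chain of secreted antibodies, was the 1 lymphocyte gene higher when adjusted over the list alone, at 9.44 ± 10.8 against 1.09 ± 1.11 CPM (SD, n = 4). Its praliciguat mean rests on replicate 3 at 25.4 CPM, with the other 3 at 2.31 to 6.71 CPM, and its log2 fold change of 3.10 was 1.91 without that library and 4.13 without placebo replicate 3. Zap70 had -0.78. Cell cycle genes (22, mean -0.24, Kif11 -0.67 and Tpx2 -0.57), erythroid genes (9, mean -0.31, Slc4a1 -0.72) and immediate early genes (25, mean -0.14, Dusp1 0.46 and Nr4a3 -1.76) were not called. For Nr4a3 the log2 difference turned between the runs of title numbers, with 0.42 in the lower and -3.29 in the upper run. The same held for oxidative stress genes (28, mean 0.20, Keap1 0.24 and Gpx1 0.47), apoptosis genes (26, mean -0.01 with median 0.00, Bcl2 -0.71 and Bcl2l1 -0.41) and stress response genes (21, mean 0.10, Ddit3 -0.44 and Xbp1 0.29). Circadian genes (19, mean 0.03, Tef 0.28 and Bhlhe41 0.18) were not called either. Leaving out 1 library brought camera calls for MHC class II presentation (without placebo replicate 3, praliciguat replicate 1 or praliciguat replicate 2, adjusted p = 0.0433, 0.0136 and 0.0089), cell cycle genes (without placebo replicate 1, placebo replicate 4 or praliciguat replicate 3, adjusted p = 0.0218, 0.000798 and 0.00108) and erythroid genes (without placebo replicate 2 or praliciguat replicate 2, adjusted p = 0.000918 and 0.00202). It did so for inflammatory cytokines, lower without praliciguat replicate 3 (mean -0.50, adjusted p = 0.0134), apoptosis genes without that library (adjusted p = 0.0366) and oxidative stress genes without praliciguat replicate 2 (adjusted p = 0.00313). Camera on ranks called cell cycle genes (adjusted p = 0.00866), erythroid genes (0.0232) and oxidative stress genes (0.0443). Without placebo replicate 3 the means of cell cycle and erythroid genes were -0.0021 and -0.049, and the lymphocyte mean was 0.052 without praliciguat replicate 3. Leaving that praliciguat library out turned the neutrophil and MHC class II means to -0.49 and -0.42, neither called (camera adjusted p = 0.396 and 0.105). With 1 library left out Mmp9 ranged from 0.24 to 1.39. Without praliciguat replicates 3 and 4 camera called circadian genes (mean 0.13, adjusted p = 0.012), and as lower apoptosis (mean -0.30, 0.012), cell cycle (mean -0.87, 0.00207), MHC class II (mean -0.69, 0.0196), inflammatory (mean -1.04, 0.000803), matrix (mean -1.02, 3.57e-28) and macrophage genes (mean -0.66, 0.00615). With an estimated correlation 0 lists were called there (camera adjusted p = 0.305 for matrix genes and 0.759 for each of the others named). Nor was any list of this paragraph called with an estimated correlation when 1 library was left out. Of the keratinocyte list 4 genes were tested, too few for the list test (Perp -0.51 and Krt10 -0.28). Lepr, the gene that carries the mutation, was at 1.03 ± 0.515 against 0.710 ± 0.189 CPM (SD, n = 4). In all, camera called 13 of 29 lists, 9 lower and 4 higher. The number was 1 with an estimated correlation, 1 with fry, 17 for camera on ranks, 10 with the filter of 1 CPM in 4 libraries and 7 without praliciguat replicate 4.

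**Figure D2:**
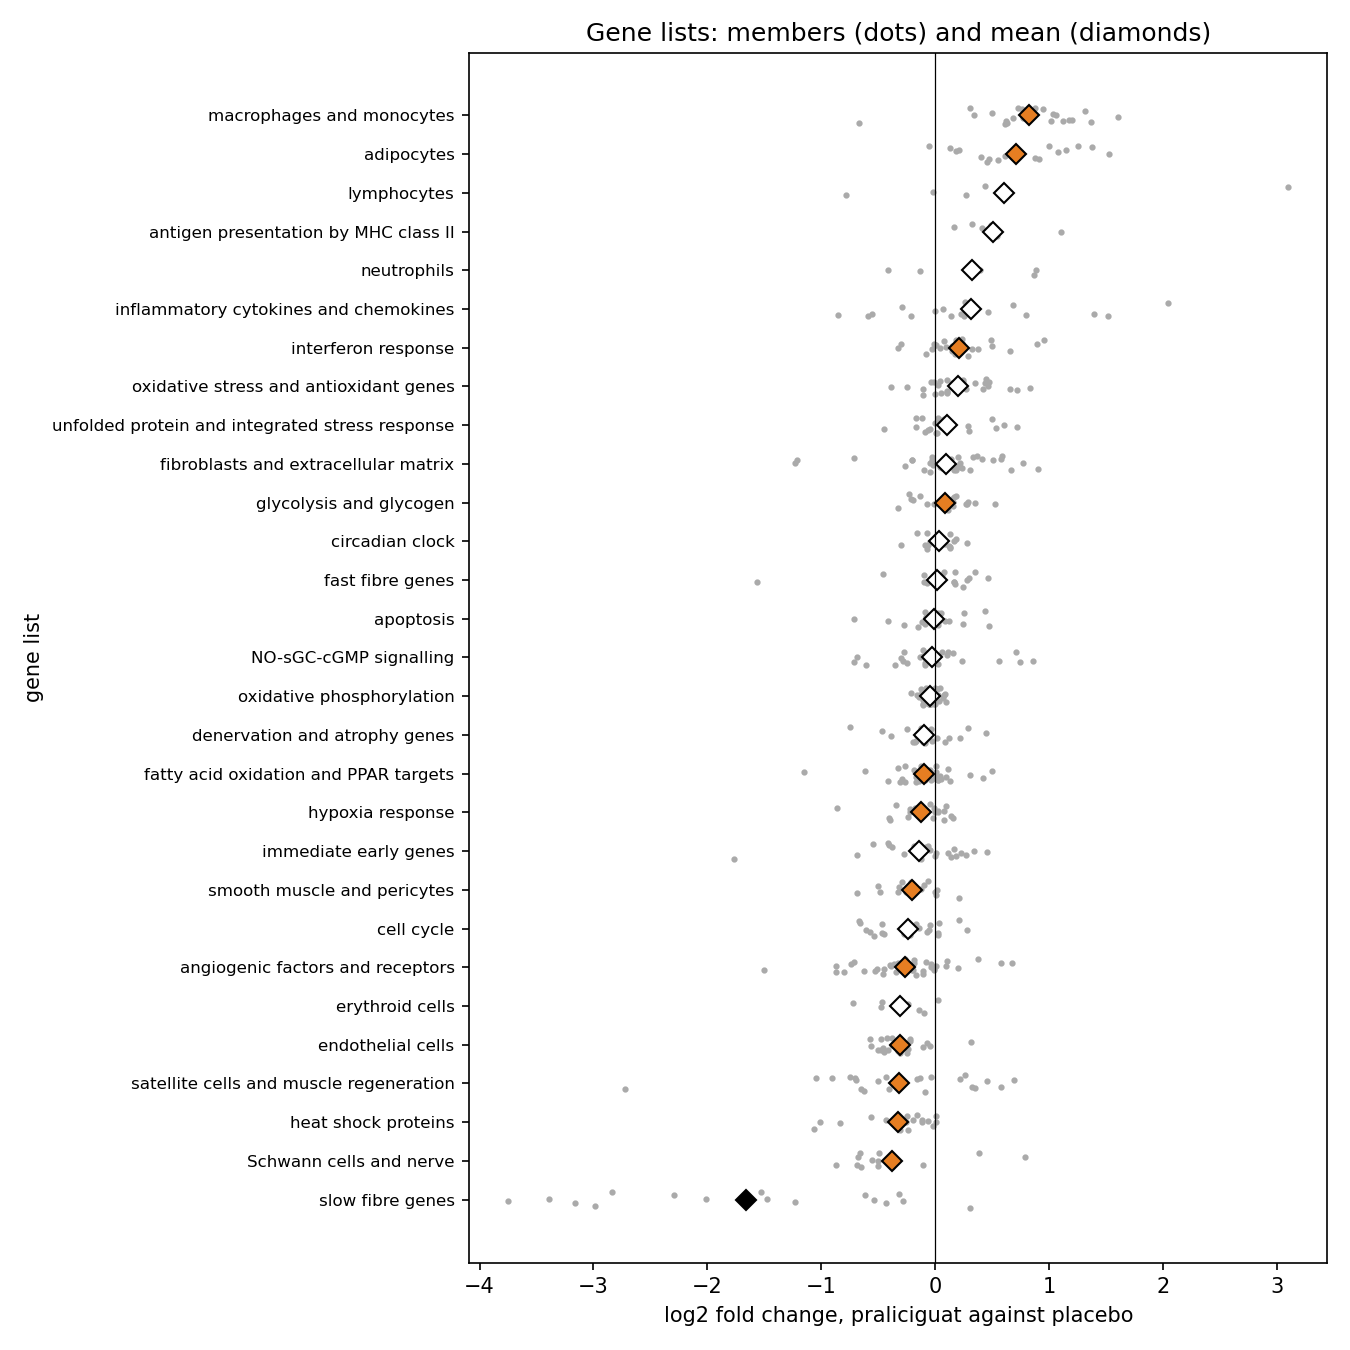
Log2 fold change (praliciguat against placebo) of each member (grey dots) and the mean of each of 29 gene lists (diamonds). Black marks the list called with both correlations (slow fibre genes, mean -1.66), orange the lists called with the preset correlation alone, and white those not called.

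**Figure D3:**
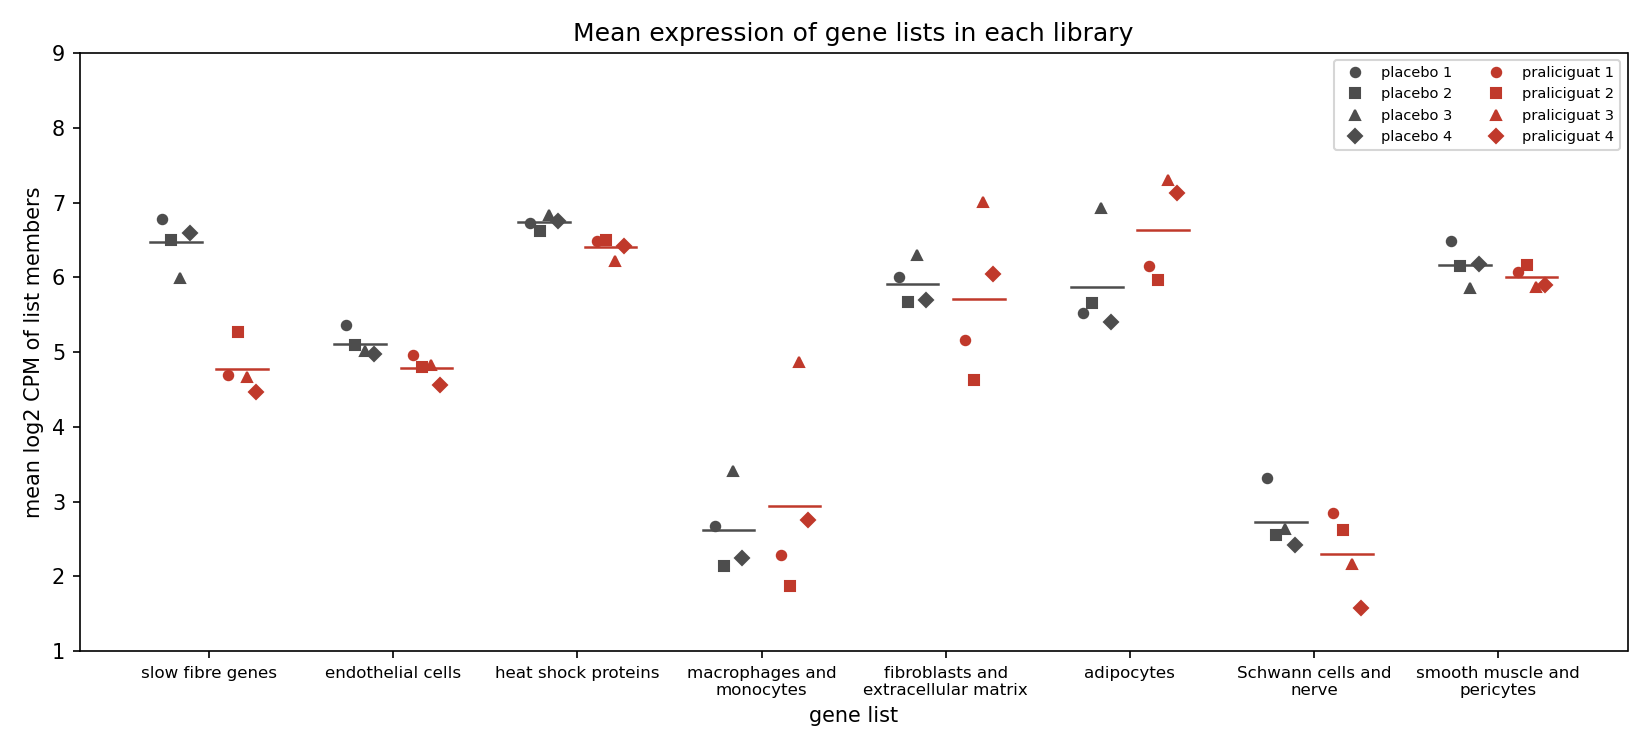
Mean log2 CPM of the members of 8 gene lists in each library, with placebo in grey, praliciguat in red and bars for group means of 4 libraries. Praliciguat replicate 3 stands at 4.86 for macrophages and at 7.01 for matrix genes.

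The library labelled praliciguat replicate 4 differed from the others in sex-linked transcripts, although every label says male. Xist, the RNA that silences one X chromosome in female cells, was at 160 CPM there (4498 counts) and at most at 0.823 CPM in the other 7 libraries. The Y-linked genes Eif2s3y, Uty and Kdm5d had 0 counts there, which allows up to 0.106 CPM each at 3 counts, and Ddx3y had 2 counts. In the other 7 libraries these 4 genes summed to 135 to 194 CPM. Without this library edgeR called 0 genes (641 at an unadjusted p under 0.05, where chance gives 686, smallest adjusted p 0.265), and the slow fibre list kept its call with an estimated correlation (mean -1.56, adjusted p = 0.0236).

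**Figure D4:**
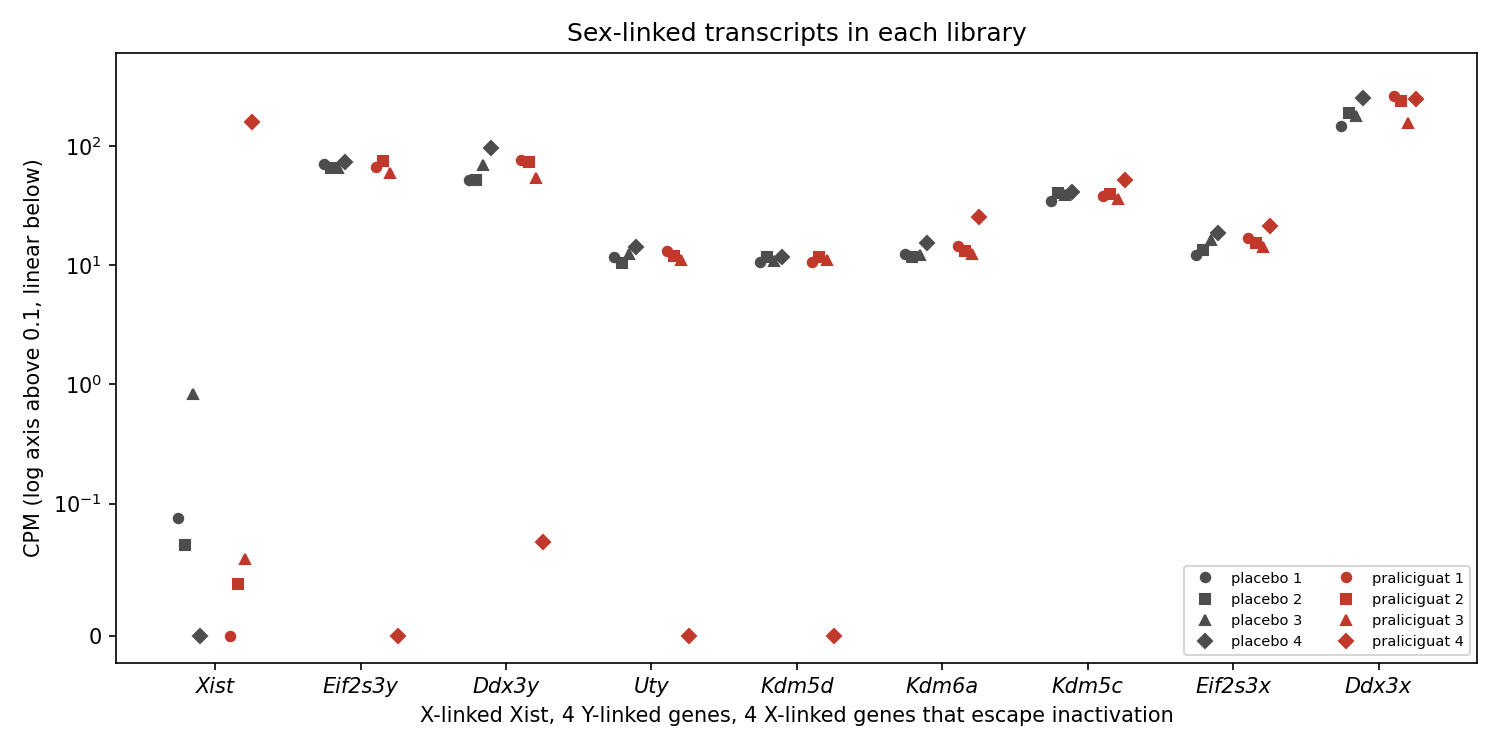
CPM of Xist, 4 Y-linked genes and 4 X-linked genes that escape silencing in each library (log axis above 0.1, linear below). The library labelled praliciguat replicate 4 (red diamond) has Xist at 160 CPM, and its 4 Y-linked genes lie at or near 0.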

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

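The tests on sex-linked genes, on the 3 cell type scores of praliciguat replicate 3, on the library left out, on slow against fast fibre genes, on dissected slow muscle and on the best list of each split were chosen after the result was seen, and the slow fibre list was picked out after it too. The gap ratio given beside some values is the distance of the most extreme library from its neighbour over the range of its group of 4, taken on the log2 scale: log2(CPM + 0.1) for genes and the mean log2 CPM for scores. The CPM values beside it are not on that scale.

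Genes of slow fibres were lower with praliciguat, by a mean of -1.66 on the log2 scale over 16 genes; 1 of the 35 splits of the 8 libraries into 4 and 4 (the real one) gave this list a mean that far from 0 (highest other 1.26), which decides nothing, since the list was picked for its difference. With the best of the 29 lists taken in each split, the real split was the 1 of 35 with the largest mean (1.66, highest other 1.65 for macrophages) and the 1 of 35 with the smallest p with an estimated correlation (3.51 as -log10, highest other 2.53). A share of 1 in 35 is the smallest that these splits can give, and both measures were chosen after the result was seen. They therefore do not exclude chance for the best list. The gap in the mean is smaller than its move with 1 library left out. The 18 splits balanced over the runs of title numbers (highest others 1.44 and 2.48) are too few for a share under 0.05. The library with female transcripts does not carry the difference (-1.56 without it), and dilution by RNA of other cells would lower fast fibre genes alike, whereas the slow score relative to the fast score differed by -1.70 and lay below all placebo libraries in 4 of 4. Slow muscle dissected along with the placebo samples cannot be told apart from an effect of the drug. The labels do not record which part of the muscle was taken. Myh7 made up at most 0.770% of adult myosin heavy chains in any placebo library. The lowest placebo share was 0.222% and the highest with praliciguat 0.0818%. To account for the difference alone, such tissue would have to be in all 4 placebo libraries. A shift of fibre type or another recovery after ischemia with praliciguat stays open, untested.

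The library labelled praliciguat replicate 4 lacked Y-linked transcripts. Loss of the Y chromosome in a male leaves Xist off, but Xist stood at 160 CPM (gap ratio 0.938, highest of the group). A mixture with male tissue is argued against by the 4 Y-linked genes, which together lay at 0.0450% of their median in the other 7 libraries; Eif2s3y, Ddx3y, Uty and Kdm5d were the lowest of their group with gap ratios of 0.965, 0.943, 0.963 and 0.980. A female animal under a male label is a candidate explanation: 3 of 4 X-linked genes that escape silencing (Kdm6a at 25.2, Kdm5c at 51.7 and Eif2s3x at 21.2 CPM) were highest in this library, and Ddx3x at 245 CPM was not. Whether the group label of that library also belongs to another sample was not tested.

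Praliciguat replicate 3 was high in macrophage and matrix genes, by 2.56 and 1.73 on the log2 scale above the mean of the other 3 praliciguat libraries. A lower share of muscle RNA would raise every other cell type alike, but the endothelial, smooth muscle and Schwann cell scores differed by 0.06, -0.17 and -0.18, with a median of -0.172. Other scores do go with a lower share in part: neutrophils, lymphocytes, satellite cells and adipocytes lay 1.91, 1.35, 1.10 and 0.89 higher and fast fibre genes 0.317 lower, so the lower share is argued against as the whole cause only. What stays open is a larger content of macrophages and matrix-forming cells in that piece of tissue, from a slower recovery or from the part dissected, and neither was tested. In the group test of 4 the score for satellite cells and regeneration (3.70 against 2.54 to 2.64) had a gap ratio of 0.915, Csf3r (5.74 against 0.568 to 0.816 CPM) one of 0.854 and Ncam1 (15.5 against 6.64 to 7.45 CPM) one of 0.864, all with this library highest.

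Of 242 groups tested 20 passed the critical value, where chance gives about 12.1, or 1 in 20. The 20 include Xist and the 4 Y-linked genes of praliciguat replicate 4, already described above. Scores share genes with the named members, so the groups are not independent and the excess over 12.1 decides nothing. In placebo replicate 3 the scores of inflammatory cytokines (2.37, gap ratio 0.914) and adipocytes (6.92, gap ratio 0.838) and the genes Csf3r (2.13 CPM, gap ratio 0.964), H2-DMb1 (2.44 CPM, gap ratio 0.854) and Slc7a10 (15.4 CPM, gap ratio 0.891) were highest of the group. Placebo replicate 1 was highest for Spns3 (1.56 CPM, gap ratio 0.866) and Cryab (973 CPM, gap ratio 0.867), and placebo replicate 2 for Eci1 (186 CPM, gap ratio 0.830) and Acaa2 (358 CPM, gap ratio 0.873). Placebo replicate 4 was highest for Pde10a (5.08 CPM, gap ratio 0.865) and lowest for Cdh5 (168 CPM, gap ratio 0.913). Praliciguat replicate 2 was highest for Ngfr (6.22 CPM, gap ratio 0.883).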

How the results depend on the processing

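Among the alternatives to the processing, the tests chosen only after results were seen were those without praliciguat replicates 3 and 4, those with an estimated correlation and libraries left out, and those of Myh7, Tnnc1, Tpm3, Casq2 and Myh4. Without praliciguat replicates 3 and 4, both of the upper run of title numbers, group and run were partly confounded. Of 90 named genes 81 kept their direction under every alternative run, and of 29 gene lists 13 did. The median log2 fold change of all genes was 0.02 with TMM, 0.02 with DESeq2 size factors and 0.01 with upper quartile scaling. Genes higher numbered 0, except 13 with DESeq2 and 6 without praliciguat replicates 3 and 4, and 0 to 0 with 1 library left out. Genes lower numbered 0, except 113 with DESeq2, 11 at an adjusted p under 0.1, 3 with the run as a block, 2 with limma-voom, 2 with quality weights and 79 without praliciguat replicates 3 and 4; with 1 library left out they ranged from 0 to 5. DESeq2 leaves out 4305 of 18273 genes from adjustment and uses its own spread model, and 123 of its 126 calls had an unadjusted p under 0.05 in edgeR; otherwise the cause was not tested. Camera called 13 lists; the number was 1 with an estimated correlation, 1 with fry, 17 for camera on ranks, 13 with DESeq2 size factors, 10 with the filter of 1 CPM in 4 libraries, 11 with the run as a block, 14 without praliciguat replicates 3 and 4, and 7 to 16 with 1 library left out. With an estimated correlation it was 0 without praliciguat replicate 3, 0 without praliciguat replicates 3 and 4, and 1 without any one of the other 7 libraries, such as placebo replicate 3 or praliciguat replicate 4. The slow fibre list kept its call in every alternative with the preset correlation (mean -1.86 to -1.55 with 1 library left out). The endothelial list had a mean of -0.31 (-0.37 to -0.21 with 1 library left out) and the angiogenic list -0.26 (-0.40 to -0.21). Both lost their calls with an estimated correlation and with fry, which do not move the mean. Their members vary together, with estimated correlations of 0.473 and 0.0837 against the preset 0.01. The slow fibre list had 0.252 and kept its call in both tests, so the size of the correlation alone does not tell which list loses its call. Of 433 results of lists under alternatives, 66 lost a call, 3 of them with a turned direction, and 27 gained one, 5 of them with a turned direction. In 2 more the direction turned and the call held.

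Without praliciguat replicates 3 and 4 log2 fold changes were -0.87 for Aif1, -0.48 for Csf3r, -0.72 for Ctss, -0.56 for H2-DMb1, -0.70 for Ccl8, 0.024 for Gucy1a1, 0.12 for Prkg1 and 0.010 for Kdr. With 1 library left out the ranges were -0.34 to 1.77 for Aif1, -0.61 to 1.47 for Csf3r, -0.38 to 1.51 for Ctss, -0.13 to 1.07 for H2-DMb1, -0.79 to 3.12 for Ccl8, -0.19 to 0.085 for Gucy1a1 and -0.37 to 0.047 for Pax7. Among lists, means without praliciguat replicates 3 and 4 were -0.66 for macrophages, -0.79 for neutrophils, -0.18 for lymphocytes, -0.69 for MHC class II, -1.04 for inflammatory cytokines, -0.031 for interferon response, -1.02 for matrix genes (-0.14 with the run as a block), 0.022 for oxidative phosphorylation, 0.067 for fatty acid oxidation, -0.19 for oxidative stress and -0.20 for stress response. With 1 library left out, means ranged from -0.38 to 1.16 for macrophages, -0.49 to 0.67 for neutrophils, -0.42 to 0.88 for MHC class II, -0.50 to 0.68 for inflammatory cytokines, -0.024 to 0.34 for interferon response and -0.51 to 0.35 for matrix genes. The ranges were -0.063 to 0.027 for cGMP signalling, -0.040 to 0.087 for fast fibre genes, -0.23 to 0.017 for denervation, -0.041 to 0.31 for oxidative stress, -0.18 to 0.060 for apoptosis, -0.010 to 0.19 for stress response and -0.047 to 0.12 for circadian genes. Without praliciguat replicate 3 alone, which had the highest scores of the immune and matrix lists, all of these lists turned except lymphocytes; neutrophils turned without placebo replicate 1 too. Why the results moved was not tested, so the cause was not tested for any of them. In the simulated check of the pipeline, 58.8% of genes changed by 1 on the log2 scale and 94.8% of those changed by 2 were recovered. Genes were drawn independently in that check, so recovery in the real libraries can differ.

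No analysis that pairs single libraries was possible because the replicate numbers were given in accession order and pair nothing across groups. The run of the title numbers, which holds libraries of both groups, entered as a block in an alternative.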

Other observations

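The tests chosen only after results were seen are those behind the genes of this paragraph and the counts of skin genes and of near-identical or overlapping genes; the counts over splits were set before. Among the genes that DESeq2 called lower, beyond the rule for named genes and picked out after their values were seen, were Ostn, the muscle-secreted peptide musclin (log2 fold change -2.20 ± 0.35 SE, adjusted p = 4.20e-07), Apln, the endothelial peptide apelin (-1.50 ± 0.35, adjusted p = 0.00607), and Ldhb, the heart-type lactate dehydrogenase subunit (-0.92 ± 0.22, adjusted p = 0.00926). In edgeR their adjusted p was 0.122, 0.341 and 0.301.

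Transcripts of hair follicle and skin appeared in praliciguat replicate 2: Krt71 had 156 counts, Krt25 112, Tchh 185 and Krt5 71. The other 7 libraries had at most 1, 1, 7 and 3 counts of them.

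Of the 35 splits of the libraries into 4 and 4, 9 gave at least the 778 genes that passed an unadjusted p under 0.05, and the highest other split gave 3153. The adjusted threshold of edgeR was passed by 0 genes in the real split and by 0 in the highest other, so that all 35 reach this count by construction and it decides nothing. For DESeq2, 7 of the 35 splits called at least the 126 genes of the real split, and the highest other called 1358. For camera with the preset correlation, 23 of the 35 splits called at least 13 lists, and the highest other called 19. Chance cannot be excluded for the 778 genes, the 126 genes and the 13 lists. The split with 3153 and 1358 genes sets placebo replicates 1 and 3 with praliciguat replicates 3 and 4 against the rest. It follows a structure of the samples that crosses the groups, seen on the first principal component with 42.5% of the variance. That component ran from -35.9 in praliciguat replicate 2 to 59.8 in praliciguat replicate 3. The second component held 18.5% and separated the groups, with 8.40 to 30.9 in placebo and -29.8 to -1.37 with praliciguat. Its separation was not tested. The split between the lower and the upper run of title numbers gave 1955 genes at an unadjusted p under 0.05, 267 with DESeq2 and 18 lists. With that run as a block edgeR had 980 genes at an unadjusted p under 0.05 and 3 called, and the slow fibre list kept its call (adjusted p = 0.0216 with an estimated correlation).

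Some genes with near-identical or overlapping relatives had counts near 0 in some libraries and high counts in others; whether reads were divided differently or transcripts were absent was not tested. Eif3j1 had 560 and 563 expected counts in placebo replicates 2 and 3 and at most 0.99 in the other 6 libraries. Amd1 had 337 in placebo replicate 4 and at most 0.01 elsewhere, and Cers1 had 0.18 in placebo replicate 4 against 232 to 505 elsewhere; Gdf1, which overlaps it, had 377 in that library. Hbb-b1 had 0.9 expected counts in praliciguat replicate 1 and 701 to 4308 in the others.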
